A study of Mus musculus with 6 samples.

How the data were processed

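RNA from 6 samples of HM1 cells, a mouse embryonic stem (ES) cell line, was measured on 1 Affymetrix whole-transcript array each. Per the labels' protocols, the cells grew in 15% serum with LIF at 1000 U/ml, were transfected with a puromycin-resistance plasmid, and were kept in puromycin at 1 ug/ml for 3 days, and 5 ug of total RNA was labelled per sample. The titles give 3 replicates of the empty vector (control) and 3 of the Prmt6 plasmid (Prmt6 overexpression). They do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

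The deposited values are log2 signals, rounded to 2 decimals, from robust multi-array average (RMA) processing, per the submitters' processing notes, which give no version. RMA corrects background, equalizes the distributions of the arrays and summarizes the probes of each probe set, so values from the same array run are comparable between arrays and a change shared by most genes would be largely removed. The software and background settings are not given in the sources used here. The table held 35556 probe sets with values from 0.84 to 14.38 and 0 missing values. Array medians lay between 5.60 and 5.62 in control and between 5.54 and 5.59 in overexpression, so a small offset between the groups remained. Detection calls were not used here, so a low value gives no separation of signal from background, and the number of arrays limits the precision.

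Gene names came from the platform annotation of 2016. It gave 1 symbol for 21789 probe sets and several for 1621, and 12146 were not named. Of the single-symbol probe sets, 21698 matched the mouse reference annotation (GRCm38.p6) by gene identifier and 91 did not, and 0 symbols changed. That annotation was used for names and for which genes neighbour each other. Each of 19938 genes was represented by its single-symbol probe set with the highest mean over the 6 arrays, and 999 genes had more than 1 such probe set. In 0 genes were probe sets called in opposite directions. Of 130 called genes with more than 1 probe set, 118 had all of them moving the same way. Probe sets with several symbols were left out of the gene-level comparison, and so were unnamed ones.

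Overexpression was compared with control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, constant variance prior), two-sided, without covariates and without a filter on dim genes. P-values were adjusted over all genes by the Benjamini-Hochberg method, with 0.05 as the threshold. Fold changes are overexpression over control, as log2 differences ± SE. Rounding residue was removed from them before signs were read. Gene lists were tested with limma's camera (preset correlation 0.01), two-sided, adjusted over 22 lists of at least 5 measured genes. Counts of members adjusted over the list alone are given beside those over all genes. Camera was also run with a correlation estimated from the data, and fry was run as a further alternative. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

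The comparison, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes Prmt6, the 12 largest rises and 12 largest falls among genes that pass the threshold and whose arrays do not overlap between groups, skipping and counting predicted genes. It adds up to 4 passing members of each list with the largest change, or the member with the smallest p where none passes, and 10 genes named in any case. Ties were taken in alphabetical order. It gave 99 genes, with 0 predicted genes skipped among the rises and 6 among the falls. Of the 10 genes named in any case, 9 were measured on a single-symbol probe set, and the other is not reported here. List members named beside these genes were chosen after their values were seen and were not refitted one by one under the alternatives.

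Alternatives were a replicate block, leaving out each array in turn, filters at the 30th percentile and at the median of the gene means, centring arrays on their medians, quantile normalization, the mean of a gene's probe sets, every probe set on its own, a trended and robust variance prior, array weights and stricter thresholds. The procedure was tested on simulated data for this comparison over 19938 genes, in 5 runs with 50 genes changed at each size. It recovered 14.0% of genes changed by 0.3 on the log2 scale, 76.8% at 0.5, 100.0% at 1 and 100.0% at 2. The mean share of unchanged genes among its calls was 5.34%, and 1.82% of unchanged lists had p under 0.05. Genes were simulated independently of each other, so the share for lists does not cover correlation between genes. Each run held 200 changed genes, against 2052 called in the data, so recovery in the data may differ.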

Results

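Gene expression was profiled in HM1 mouse ES cells carrying an empty vector (3 arrays, control) or a Prmt6 expression plasmid (3 arrays) after 3 days of puromycin selection. Prmt6 is a nuclear arginine methyltransferase that modifies histones. The cells were kept with LIF, a cytokine that holds mouse ES cells undifferentiated. Pearson correlations across all probe sets, which are not independent replicates, ran from 0.991 to 0.992 between control arrays, from 0.986 to 0.990 between overexpression arrays and from 0.980 to 0.987 between the groups. The median SD over genes was 0.0819 in control and 0.115 in overexpression (log2, n = 3 each). The leading principal component, with 58.3% of the variance, separated the groups.

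The comparison asked which genes differ in expression between ES cells with the Prmt6 plasmid and ES cells with the empty vector. With the Prmt6 plasmid, the smooth muscle actin gene Acta2 rose 23.1-fold (4.53 ± 0.088 on the log2 scale, n = 3 per group, limma) and the epithelial keratins Krt18 and Krt8 rose 9.34-fold and 7.43-fold. All 6 measured genes of the 16 on the 2-cell-like list fell, Tmem92 by the most (-1.86 ± 0.17). Nanog and Sox2, transcription factors of the undifferentiated state, fell by 0.34 and 0.29, while Pou5f1, at 0.19 ± 0.079, did not pass. The Nanog call ended without control replicate 1, 2 or 3 (adjusted p from 0.0552 to 0.0765), and that of Sox2 without any 1 array (0.0549 to 0.163) and with arrays centred on medians (0.111).

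Prmt6 was read by 1 probe set, at log2 values of 6.84, 6.58 and 7.12 in the control arrays and 7.32, 7.40 and 7.33 in the overexpression arrays. It rose 1.42-fold (0.50 ± 0.13 on the log2 scale, adjusted p = 0.0406), and 681 other genes past the threshold rose by more. Whether this probe set lies within the cloned sequence was not analysed here. The Prmt6 call ended without control replicate 1 (adjusted p = 0.116), control replicate 2 (0.0954), overexpression replicate 1 (0.0893), replicate 2 (0.119) or replicate 3 (0.0788), and held without control replicate 3 (0.0108). It also ended with the replicate block (0.0615).

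With the Prmt6 plasmid, 1405 of 19938 genes rose and 647 fell, so that 68.5% of the calls were rises. All 2052 called genes had 3 overexpression arrays on 1 side of the 3 control arrays, as had 29.7% of all genes, where chance gives 10%. Rises of at least 1.5-fold numbered 532 and falls 134, and at 4-fold there were 27 rises and 1 fall. At an unadjusted p under 0.05 there were 4889 genes, against 997 by chance. Centring each array on its median gave 1838 rises and 447 falls (80.4% rises). Rises numbered 862 without control replicate 1 and 898 without control replicate 3, and falls numbered 280, 321, 297 and 328 without control replicates 1, 2 and 3 and overexpression replicate 2. Falls numbered 990 with genes under the 30th percentile left out, 1079 with those under the median left out, 1115 with a trended and robust variance prior and 1098 with array weights.

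Acta2, the actin of smooth muscle, had the largest rise, 23.1-fold from 6.62 ± 0.13 to 11.15 ± 0.07 (log2, SD, n = 3, adjusted p = 1.75e-07). Tagln, an actin-binding protein of smooth muscle, rose 9.78-fold from 7.92 ± 0.07 to 11.21 ± 0.087. The partner keratins of simple epithelia, Krt18 and Krt8, rose 9.34-fold and 7.43-fold. Among the other large rises were Pmp22, a membrane protein of myelin (12.2-fold), Ptgs2, which makes prostaglandin precursors (8.30-fold), and Gsn, which severs actin filaments (7.55-fold). The phospholipid-binding annexins Anxa5 and Anxa2 rose 7.76-fold and 6.29-fold. The protease Prss23 rose 6.33-fold, the mitochondrial carrier Slc25a24 6.28-fold and the matrix glycoprotein Thbs1 6.20-fold. Adjusted p for these 12 genes lay between 1.75e-07 and 2.35e-06. The fibroblast collagens Col1a1 and Col1a2 rose by 1.34 and 0.98 on the log2 scale in the same arrays.

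Of the fibroblast list, 11 of 19 measured genes rose and 8 did not pass (13 higher and 0 lower adjusted over the list alone, camera adjusted p = 1.46e-10, adjusted p = 0.101 with an estimated correlation). Its largest rises after Acta2 and Tagln were those of Vim, an intermediate filament protein (1.62 ± 0.067), and Lox, which crosslinks collagen (1.51 ± 0.078). Vim and Acta2 are also made by other cell types. The fibrillar collagens Col1a1, Col1a2 and Col3a1 rose by 1.34, 0.98 and 0.36, while Thy1 was at 0.043 and S100a4 at -0.017 without passing. Collagens named beside other lists below are part of this mixed picture and do not show on their own that fibroblasts were present.

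Tmem92, a transcript of the 2-cell-like state that appears in rare ES cells, had the largest fall among named genes, from 6.57 ± 0.18 to 4.71 ± 0.35 (log2, SD, n = 3, adjusted p = 0.000236). All 6 measured genes of the 2-cell-like list fell (0 higher and 6 lower adjusted over the list alone, camera adjusted p = 7.00e-09, adjusted p = 0.101 with an estimated correlation). Besides Tmem92 they were Tdpoz3 (-1.70 ± 0.15), Usp17la (-1.45 ± 0.19), Usp17lc (-1.15 ± 0.11), Tcstv3 (-1.11 ± 0.15) and Zfp352 (-0.56 ± 0.08). The list holds 16 genes, and Dux and its Zscan4 genes were among those not measured, so the falls cover only part of it. Fibroblast collagens rose in the same arrays, Col1a1 by 1.34 and Col1a2 by 0.98. The pluripotency network list had a median change of 0.0067 there, with 3 of 31 genes higher and 6 lower. That median argues against dilution of the ES cells by fibroblasts as the source of falls this large. Other large falls were those of Eif4a3l1 (-1.81 ± 0.17), Pramel19 (-1.60 ± 0.12), Pramel20 (-1.53 ± 0.14), Usp17lb (-1.37 ± 0.11), Trim36 (-1.22 ± 0.067), the microRNA gene Mir380 (-1.41 ± 0.18) and Arg2, the mitochondrial arginase (-1.32 ± 0.077). The Usp17l, Tdpoz, Pramel and Tcstv families hold similar copies whose probe sets may share signal, so the values of single members are uncertain.

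**Figure D1:**
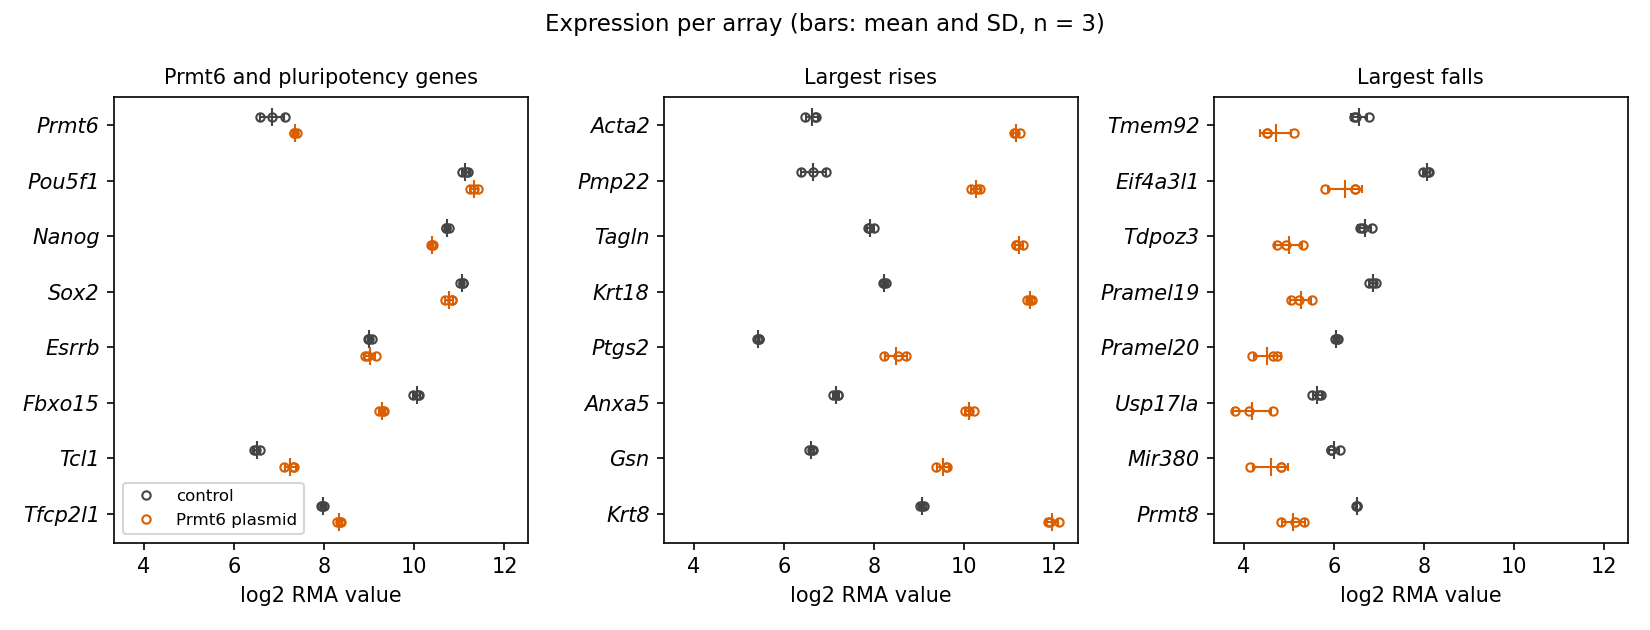
Log2 RMA value (x axis) of 8 genes per panel, with circles for single arrays and bars for the mean and SD of 3 control arrays and 3 arrays of the Prmt6 plasmid. Genes of the panels of largest rises and falls were chosen among those whose control and plasmid arrays do not overlap. The arrays overlap for Esrrb, which was named in any case.

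Of the pluripotency network, 3 of 31 measured genes rose, 6 fell and 22 did not pass (4 higher and 7 lower adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.521). Nanog and Sox2, core transcription factors of ES cells, fell by 0.34 and 0.29 on the log2 scale (adjusted p = 0.0153 and 0.0485). Fbxo15, a marker of undifferentiated ES cells, fell by 0.77, and Rif1, a telomere-associated protein, fell by 0.35. Tcl1, a coactivator of Akt, and Tfcp2l1, a transcription factor of naive pluripotency, rose by 0.74 and 0.37, and the fibroblast collagen Col1a1 by 1.34. Pou5f1, the gene of Oct4, was at 0.19 ± 0.079 (adjusted p = 0.190), Klf4 at -0.10 ± 0.09 (0.543) and Esrrb at 0.0067 ± 0.083 (0.974) without passing, the last at -0.044 under quantile normalization. The list's median of 0.0067 had the opposite sign to its mean of -0.017 and to camera's downward direction, and under quantile normalization it passed downward (median -0.044, adjusted p = 0.0283). Calls ended for Sox2 without any 1 array (adjusted p from 0.0549 to 0.163) and with arrays centred on medians (0.111), for Nanog without control replicate 1 (0.0564), 2 (0.0552) or 3 (0.0765), for Rif1 without every array but overexpression replicate 1 (0.0503 to 0.0855), and for Tfcp2l1 without control replicate 1 (0.0593) or 3 (0.0508). With the replicate block the calls of Nanog (0.0615), Sox2 (0.116) and Rif1 (0.0639) ended as well. Pou5f1 passed with a trended and robust variance prior (0.0362).

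Of the primed epiblast list, 1 of 15 genes rose, 3 fell and 11 did not pass (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.00540, downward, adjusted p = 0.157 with an estimated correlation). The falls were those of Wnt8a (-0.56 ± 0.11), Otx2, a transcription factor of the primed state (-0.46 ± 0.071), and Dnmt3b, a de novo DNA methyltransferase (-0.30 ± 0.078), and the tight-junction gene Cldn6 rose (1.25 ± 0.088). The Wnt8a call ended without control replicate 3 (adjusted p = 0.0540), and that of Dnmt3b without every array but overexpression replicate 1 (0.102 to 0.151) and with arrays centred on medians (0.101). Of the germline list, 1 of 22 genes rose, 5 fell and 16 did not pass (1 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.00224, downward, adjusted p = 0.278 with an estimated correlation). Hormad1, a meiotic chromosome protein (-0.79 ± 0.15), Mov10l1, a helicase of the piRNA pathway (-0.61 ± 0.10), the RNA-binding protein gene Dazl (-0.49 ± 0.081) and Slc25a31 (-0.49 ± 0.084) had the largest falls among its members that passed. Sycp3 was at -0.54 ± 0.17 (adjusted p = 0.0885) without passing. In the arrays where both lists moved down, the fibroblast collagens Col1a1, Col1a2 and Col3a1 rose by 1.34, 0.98 and 0.36. Of the whole fibroblast list, 11 of 19 measured genes rose there and 8 did not pass, among them Lum (0.063) and Postn (0.22). The pluripotency network list had a median change of 0.0067 in these arrays.

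Of the endoderm list, 11 of 26 genes rose and 15 did not pass (13 higher and 0 lower adjusted over the list alone, camera adjusted p = 1.83e-06, adjusted p = 0.114 with an estimated correlation). Its largest rises were in genes of the extracellular matrix that other cell types also make, namely the collagen chaperone Serpinh1 (1.69 ± 0.11), the basement-membrane collagens Col4a1 (1.49 ± 0.11) and Col4a2 (2.82-fold) and the matrix protein Sparc (1.28 ± 0.073). Cubn (0.94 ± 0.11), Dab2 (0.77 ± 0.083), Plat (0.73 ± 0.10), Lamb1 (0.53 ± 0.071) and Pdgfra (0.42 ± 0.10) rose as well. The endoderm transcription factors Sox17 and Gata6 rose by 0.58 and 0.43, and Gata4 was at 0.26 ± 0.082 (adjusted p = 0.0884) without passing. Foxa2, Foxa1, Hnf4a and Sox7 did not pass either, at 0.047, -0.017, -0.017 and -0.023. Of the trophoblast list, 8 of 20 genes rose, 1 fell and 11 did not pass (11 higher and 2 lower adjusted over the list alone, camera adjusted p = 3.37e-05, adjusted p = 0.114 with an estimated correlation). The keratins Krt8 (2.89 ± 0.085), Krt19 (2.61 ± 0.081) and Krt7 (2.34 ± 0.11), found in many simple epithelia, led it, followed by the transcription factor Hand1 (0.98 ± 0.072), the placental gene Plac1 (0.80 ± 0.082), the transcription factor Tead4 (0.67 ± 0.091), the ligand Wnt7b (0.66 ± 0.071) and the imprinted Peg10 (0.53 ± 0.078). Its 1 fall was that of the growth factor receptor gene Fgfr2 (-0.43 ± 0.096, adjusted p = 0.0264). Among transcription factors of the list that did not pass, Gata3 was at 0.52 ± 0.15, Cdx2 at 0.26 ± 0.079, Tfap2c at -0.22 ± 0.069 and Elf5 at -0.25 ± 0.12 (adjusted p = 0.0593, 0.0810, 0.0876 and 0.242), so that they lay on both sides of 0. The fibroblast-list genes Col1a1 and Col1a2 rose in the same arrays as both lists.

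Of the primitive streak and mesoderm list, 5 of 25 genes rose and 20 did not pass (6 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0151, adjusted p = 0.161 with an estimated correlation). Bmp4, a signalling ligand (1.23 ± 0.08), Hand1 (0.98 ± 0.072), Tbx20 (0.89 ± 0.093) and Eomes, a T-box factor (0.55 ± 0.086), had its largest rises, in the arrays where Col1a1 rose by 1.34. The list's call ended without overexpression replicate 3 (adjusted p = 0.0557) and with genes under the 30th percentile left out (0.0636). Of the neural and ectoderm list, 4 of 28 genes rose, 2 fell and 22 did not pass (4 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.764), with falls of Neurod1 (-1.08 ± 0.076) and Dll1 (-0.60 ± 0.088) and rises of Sox11 (0.79 ± 0.094) and Msx2 (0.70 ± 0.088). Of the Hox clusters, Hoxd8 rose (0.46 ± 0.099) and 36 of 37 genes did not pass (0 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.488). The Hoxd8 call ended without control replicate 1 (0.0872) or 3 (0.0845) or overexpression replicate 2 (0.0668) or 3 (0.0585), and the list passed upward without overexpression replicate 1 (0.0387).

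Of the list of CDK inhibitors and reported PRMT6-repressed genes, 3 of 8 genes rose, 1 fell and 4 did not pass (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00648, upward, adjusted p = 0.123 with an estimated correlation). Its median change was 0.11 and its mean 0.62, and upward is the opposite direction to the repression its name refers to. Thbs1, an inhibitor of angiogenesis, rose (2.63 ± 0.071), as did the cell cycle inhibitors Cdkn2b (1.51 ± 0.08) and Cdkn2a (0.88 ± 0.10, adjusted p = 0.000992), while Cdkn1b fell (-0.30 ± 0.076). Col1a1 rose by 1.34 in the same arrays. The Cdkn1b call ended without any 1 array (0.0534 to 0.154), with arrays centred on medians (0.0867) and with the mean of its probe sets (0.119). Of the cell cycle list, Bub1 (-0.36 ± 0.075), Cenpe (-0.35 ± 0.088) and the proliferation marker Mki67 (-0.29 ± 0.069) fell and 28 of 31 genes did not pass (0 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0729). These 3 calls ended without every array but overexpression replicate 1 (0.0502 to 0.141), and those of Cenpe and Mki67 with arrays centred on medians (0.0773 and 0.0699). The list passed downward without overexpression replicate 1 (0.0194), under quantile normalization (0.000211), with a trended and robust variance prior (0.0305) and with genes under the median left out (0.0373). Of the p53 targets, 3 of 26 rose, 5 fell and 18 did not pass (4 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.180, and 0.0142, downward, under quantile normalization). Perp, a desmosome-associated protein, rose (1.01 ± 0.066), while the proapoptotic Pmaip1 (-0.49 ± 0.079), Dcxr (-0.45 ± 0.085) and the DNA repair gene Ercc5 (-0.41 ± 0.091) fell. The Dcxr call ended without control replicate 1 (0.0589) or 2 (0.0537), and that of Ercc5 without every array but overexpression replicate 1 (0.0569 to 0.0974).

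Among the other arginine methyltransferases and PRMT5 cofactors, Prmt8, a membrane-bound family member, fell (-1.41 ± 0.12), Prmt2 rose (0.58 ± 0.10) and 8 of 10 genes did not pass (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.997). The list's mean of -0.064 had the opposite sign to its median of 0.012 and to camera's upward direction, and the median was -0.021 under quantile normalization. Carm1 was at 0.02 ± 0.073, Prmt1 at 0.083 ± 0.068 and Prmt5 at -0.02 ± 0.066 (adjusted p = 0.906, 0.514 and 0.896), with Carm1 at -0.031 under quantile normalization and Prmt5 at 0.027 with arrays centred on medians. Of the Polycomb and trithorax list, 4 of 25 genes fell and 21 did not pass (1 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.00224, downward, adjusted p = 0.373 with an estimated correlation). The falls were those of the Polycomb genes Phc1 (-0.53 ± 0.07) and Bmi1 (-0.31 ± 0.076) and of the histone demethylases Kdm5b (-0.36 ± 0.074) and Kdm6a (-0.33 ± 0.07), in the arrays where the fibroblast collagens Col1a1 and Col1a2 rose by 1.34 and 0.98. Calls ended for Bmi1 without any 1 array (0.0521 to 0.141) and with arrays centred on medians (0.0683), and for Kdm5b and Kdm6a without control replicate 1, 2 or 3 or overexpression replicate 2 (0.0626 to 0.0864).

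Of the cholesterol biosynthesis list, 7 of 20 genes rose and 13 did not pass (13 higher and 0 lower adjusted over the list alone, camera adjusted p = 2.55e-07, adjusted p = 0.136 with an estimated correlation). The sterol pathway enzymes Msmo1 (0.53 ± 0.074), Tm7sf2 (0.53 ± 0.093), Ebp (0.50 ± 0.068) and Idi1 (0.47 ± 0.071) had its largest rises. Of the ERK feedback and immediate early list, 7 of 20 genes rose and 13 did not pass (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000118, adjusted p = 0.123 with an estimated correlation). The phosphatases Dusp4 (1.49 ± 0.074) and Dusp1 (1.28 ± 0.078), Phlda1 (1.47 ± 0.077) and the matrix-associated Ccn1 (1.35 ± 0.081) had its largest rises. Of the LIF-STAT3, BMP and Nodal targets, 7 of 19 rose and 12 did not pass (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000803, adjusted p = 0.114 with an estimated correlation), led by Ier3 (1.08 ± 0.076), Dusp9 (1.02 ± 0.076), Msx2 (0.70 ± 0.088) and the Nodal antagonist Lefty2 (0.65 ± 0.11). The fibroblast collagen Col1a1 rose by 1.34 in the same arrays as these 3 lists.

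Of the Wnt targets, Dkk1, a secreted Wnt inhibitor (0.61 ± 0.12), and Sp5 (0.37 ± 0.069) rose and 11 of 13 did not pass (3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.764). Of the amino acid and unfolded protein stress list, Atf3 (0.92 ± 0.075), Cth (0.60 ± 0.073) and Phgdh (0.57 ± 0.09) rose, Herpud1 fell (-0.28 ± 0.075) and 20 of 24 did not pass (4 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.521). Of the interferon response, the chemokine Cxcl10 rose (1.14 ± 0.097) and 21 of 22 genes did not pass (1 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.993). Of the glycolysis and hypoxia list, Ndrg1 rose (0.47 ± 0.09), Bnip3 (-0.49 ± 0.073), Pdk1 (-0.38 ± 0.072) and Pfkl (-0.30 ± 0.071) fell and 19 of 23 did not pass (3 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.993). Calls ended for Herpud1 without any 1 array (0.0662 to 0.184) and for Pfkl without every array but overexpression replicate 1 (0.0688 to 0.128), and for both with arrays centred on medians (0.0852 and 0.0702). Those of Dkk1 ended without control replicate 1 (0.0533) or 3 (0.0577), Sp5 without control replicate 1 (0.0594), Ndrg1 without control replicate 2 (0.0523) or 3 (0.0507) and Pdk1 without control replicate 3 (0.0575).

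**Figure D2:**
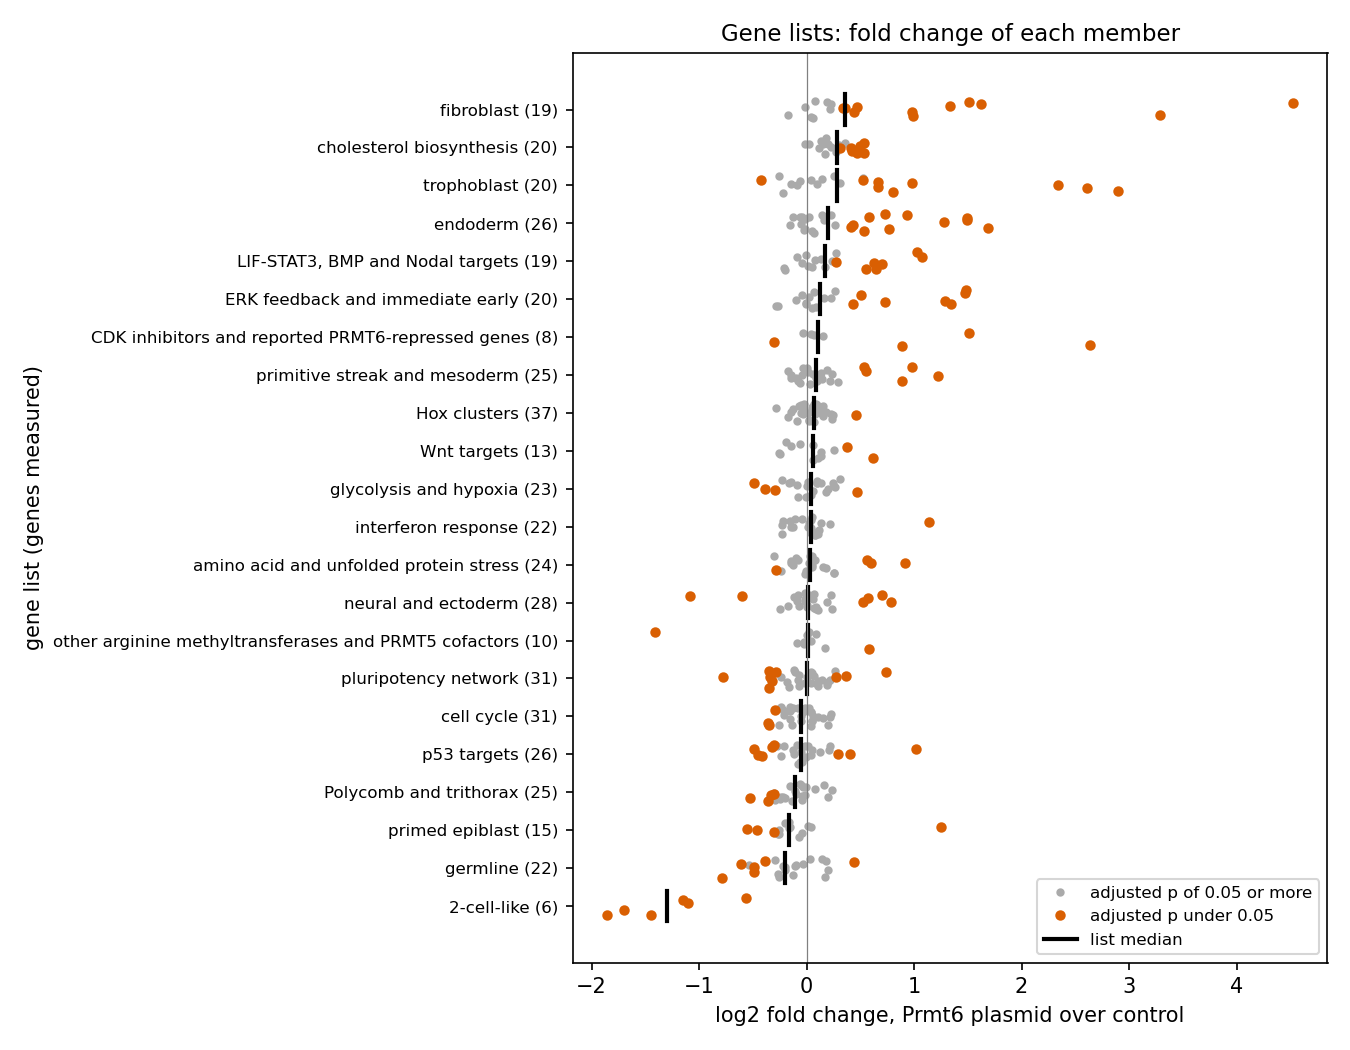
Log2 fold change (x axis, Prmt6 plasmid over control) of each measured member of the 22 gene lists (y axis, number measured in brackets), with orange dots for adjusted p under 0.05, grey dots for other members and a black bar for the list's median. The medians run from -1.30 for the 2-cell-like list to 0.36 for the fibroblast list.

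In all, 12 of the 22 lists passed with camera's preset correlation, 8 upward and 4 downward. With an estimated correlation 0 passed in limma's camera (smallest adjusted p = 0.101), 8 had an unadjusted p under 0.05, and limma's fry called 13 for movement on balance one way and 21 for change in either direction. Camera's run with an estimated correlation also has less power with 6 arrays, so calls lost there need not reflect correlation between genes. For the list of CDK inhibitors the estimate, 0.0026, lay below the preset 0.01, yet camera's unadjusted p went from 0.0032 to 0.039. Fry asks whether the members change at all, and camera whether they change more than other genes, so the counts are not alike. With 4889 of 19938 genes at an unadjusted limma p under 0.05, a fry call says little particular to a list.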

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

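The tests of splits of the arrays, of fibroblast transcripts, of 2-cell-like genes without near copies, of array labels and of Prmt6 probe sets were chosen after the result was seen. The quantile normalization test was planned.

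Probe sets that no gene-level comparison used also carried a difference between the groups. Of 13767 probe sets with several symbols or no name, tested on their own with limma, 25 were higher and 98 lower with the Prmt6 plasmid. Those with several symbols gave 7 higher and 46 lower, and unnamed ones 18 and 52.

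The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only 1 split, the real one, gave as many genes past the threshold, with 2052, and the highest of the others gave 0.

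The rise of Acta2, Tagln, keratins and annexins was weighed first. As a source of part of the rise, fibroblasts mixed into the overexpression cultures cannot be told apart from a change in the ES cells. The 3 abundant fibroblast transcripts above the arrays' lower quartile, Col1a1, Col1a2 and Col3a1, rose by a mean of 0.89 (SE 0.29 over 3 genes) on the log2 scale. The mean plus 2 SE, 1.46, exceeds the bound of 1 for excluding fibroblasts, which was set after the result was seen. Lum, Dcn and Postn, at 0.063, 0.44 and 0.22, lay below that quartile and were taken as too near the floor to decide. Over all 6 transcripts the mean was 0.57 (SE 0.20) and the mean plus 2 SE 0.96, under the bound. The outcome therefore rests on leaving these 3 out. Under quantile normalization 93.1% of genes called higher kept their call. RMA already equalizes the distributions of the arrays, so this test of between-array scaling had little room to come out otherwise. It cannot decide about scaling within that step. An effect of the Prmt6 plasmid and cells that differentiated during selection stay open, and fibroblasts stay open as a source of part of the rise. Fibroblasts as its only source are argued against by epithelial genes, on a list chosen after the largest changes were seen. Of 16 measured genes of desmosomes and epithelial junctions, 13 rose and 0 fell. Outside the 50 largest rises, 8 of the 11 remaining rose and 0 fell, with a median of 0.51.

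The fall of the 2-cell-like list was weighed next. Signal shared between near-identical copies cannot be told apart from separate falls of genes within a family, and probe sequences were not analysed here. Of Tmem92 and Zfp352, taken as members without close copies, Tmem92 has the largest fall of the list and decides nothing. That leaves Zfp352 alone, at -0.56 (SE 0.08). Tdpoz3 (-1.70), Usp17la (-1.45), Tcstv3 (-1.11) and Zfp352 are of different families, so sharing between copies is argued against as the source of all these falls. Fewer cells in the 2-cell-like state, or lower expression in each cell, may also account for the fall, and no test here separates them.

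The small rise of Prmt6 was weighed last. A wrongly labelled array is argued against, since 0 of the 6 arrays correlated better with the other group than with their own. Whether the probe set reads little of the plasmid transcript cannot be told apart from a small rise, because the gene has 1 probe set and the probe positions were not used here.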

How the results depend on the processing

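All alternatives here were planned. Replicate numbers are shared by the groups, but same-numbered samples deviated together by r of -0.019, -0.0158 and -0.117 only, and 0 of the 6 samples correlated best with their own number, so the numbers do not pair them. With the replicate block there were 1018 rises and 383 falls, Prmt6 was at 0.50 (adjusted p = 0.0615, in a range from 0.00459 to 0.119 over all settings), and 14 of 98 other named genes lost their call while all 12 lists kept theirs. Without single arrays, where fewer arrays lower the power, rises ran from 862 to 1232, falls from 280 to 763, the Prmt6 change from 0.37 to 0.64, lists past the threshold from 11 to 14 and the pluripotency median from -0.01 to 0.03. Of the 98 genes, 74 kept call and direction in all 6 refits and 22 lost their call in at least 1. Carm1 ran from -0.0033 to 0.062, Esrrb from -0.063 to 0.057, and list medians from -0.0042 to 0.063 (interferon), -0.032 to 0.11 (neural) and -0.0075 to 0.044 (arginine methyltransferases). Falls numbered 990 and 1079 with genes under the 30th percentile and the median left out, where fewer genes were tested, 1115 with a trended and robust variance prior and 1098 with array weights. Stricter thresholds left 532 rises and 134 falls at 1.5-fold, and 765 and 219 at adjusted p under 0.01. The pluripotency median changed sign, to -0.0017 above the median level, -0.044 under quantile normalization (adjusted p = 0.0283), -0.01 with means of probe sets, -0.0063 with array weights and -0.0133 with every probe set on its own. Fry for change in either direction, which asks only whether members change at all, called that list (median 0.0067, adjusted p = 0.000114) and 21 lists in all. Camera with an estimated correlation, which compares a list with other genes, called 0, and 8 had an unadjusted p under 0.05. Above the median level, medians turned to -0.043 (interferon) and -0.15 (Wnt). Quantile normalization turned the arginine methyltransferases to -0.021, amino acid stress to -0.013, Esrrb to -0.044 and Carm1 to -0.031. Array weights turned the methyltransferases to -0.012, Esrrb to -0.0063 and Carm1 to -0.0018, and centring turned Prmt5 to 0.027. None of these genes and lists had passed the test, and except where stated the cause was not tested. The glycolysis median was 0 with every probe set on its own. The deposited values carry no signal over background, so the level below which a gene is not measured is unknown.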

Other observations

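The lists here were chosen after the genes with the largest changes were seen, and so was the comparison with other microRNA genes. The tests of host transcripts and of list members beyond the 50 largest rises were set before their results were seen.

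Of 24 measured targets of SRF and its coactivator MRTF, which control actin and muscle genes, 18 rose and 6 did not pass (limma, adjusted over all genes), with a median of 1.12 on the log2 scale. They included Flnc (2.11), Cald1 (1.93), Fhl2 (1.83), Tpm1 (1.76), Cnn2 (1.47) and Vcl (0.97), while Srf was at 0.11 and Actb at 0.20 without passing. Of 23 targets of YAP and TEAD, which respond to cell spreading and tension, 15 rose and 8 did not pass, among them F3 (2.08), Crim1 (1.98), Axl (1.96) and Ankrd1 (0.84), while Ccn2 was at 0.23 without passing. Genes of desmosomes and epithelial junctions rose as well, 13 of 16, including Dsp (2.06), Cldn4 (1.49) and Cdh1 (0.45). In the same arrays 10 of 14 genes of the epithelial-mesenchymal transition rose, such as Cdh2 (0.81), Mmp14 (1.17) and Zeb2 (0.88). Twist1 was at 0.22, Snai1 at 0.033, Zeb1 at -0.15 and Snai2 at -0.29 without passing. The fibroblast transcripts Col1a1 (1.34), Col1a2 (0.98), Dcn (0.44) and Col3a1 (0.36) rose in the same arrays as these lists, while Lum (0.063) and Postn (0.22) did not pass. Dcn, Lum and Postn lay below the arrays' lower quartile. Acta2 and Tagln of the SRF list and Vim, Fn1, Lox and Twist1 of the transition list are also on the fibroblast list. Among genes other than the 50 largest rises, camera called the 11 remaining junction genes upward (adjusted p = 3.36e-10). The transition list had 0 members among those 50, so leaving them out did not test it further (adjusted p = 5.60e-11). Both calls were lost with an estimated correlation (adjusted p = 0.0506).

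A candidate explanation is higher activity of SRF with MRTF, or of YAP with TEAD. Without the 50 largest rises, camera still called the remaining targets upward, with adjusted p of 2.25e-17 for SRF and MRTF and 2.40e-10 for YAP and TEAD. With an estimated correlation these were 0.00360 and 0.0506, so the second call was lost. The lists overlap in function, and transcript levels do not show which factor was active. Fibroblasts stay open as another source of part of the rises of these targets, since 3 of their abundant transcripts rose by a mean of 0.89.

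MicroRNA genes between the imprinted genes Dlk1 and Dio3 fell together. Of 40 there, 21 fell and 19 did not pass (median -0.41), against 16 falls and 246 that did not pass among 262 other microRNA genes (median -0.053). The other microRNA genes had lower signals, with a median control level of 4.62 against 5.95 in the cluster, so each cluster gene was also compared with the 20 others closest in control level. Draws matched in this way had a median control level of 5.89 and a median change of -0.11, and a share of 1e-05 gave as low a median as the cluster, the smallest share that 100000 draws can give. This argues against a shift of all microRNA probe sets as the whole source, while a smaller general fall stays open and neighbouring genes are not independent. The 2 measured noncoding host transcripts, Meg3 (-0.66 ± 0.077) and Rian (-0.67 ± 0.11), both fell, with a median of -0.67. Lower transcription of the cluster may therefore account for the falls, with the limit that the microRNA probe sets could read the host RNA itself.

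Of 25 measured imprinted genes, 8 rose, 2 fell and 15 did not pass, including rises of Igf2 (2.22), Nnat (1.76), Dio3 (0.91), Sgce (0.79) and Ndn (0.68), while Dlk1 was at 0.14 without passing. The whole list was called upward by camera (adjusted p = 0.00356), and without the 50 largest rises, 2 of which are on it, the call was lost (adjusted p = 0.0674, and 0.254 with an estimated correlation). Col1a1 and Col1a2 rose by 1.34 and 0.98 in the same arrays.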
